A study of Mus musculus with 8 samples.

How the data were processed

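Whole lungs of BALB/c mice carrying an inducible IL-1b transgene were profiled on a 1-colour expression array, with 3 arrays from mice given water and 5 from mice given doxycycline (dox), which switches the transgene on. Per the labels, lungs were taken after 7 days of treatment at about 12 weeks of age, whereas the header of a deposited table names 5 weeks; the difference was left open. Total RNA was amplified to biotin-labelled cRNA, per the labels' protocols. The deposited values are intensities on a linear scale, 1 per probe set and array, made by the authors with RMA per the submitters' processing notes; the version is not given in the sources used here. RMA normally corrects background, equalises the distributions of the arrays and summarises probes, so a change in total RNA per lung cannot be seen in such values and the brightest transcripts are compressed. Quartiles were close between arrays: medians of intensity ran from 40.8 to 41.9. The number of arrays limits the precision, and no calls of detection over background were used here.

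The gene symbols of the probe sets came from the annotation columns of the deposited text table, which is of another kind than the intensity values and was joined by probe set name. A further 8 columns of intensity values in that table carry names that match no sample label, and they were not used. Of 43681 probe sets with values, 36993 had 1 gene symbol, 1 had several and 6687 had none. Symbols were brought up to date with a table of RefSeq names of assembly GRCm38.p6, used for names only: 17218 probe sets were named through their accession, 13435 through a current symbol and 1890 through an older symbol, and 4450 kept the symbol of the array. No coordinates were used. Of the 27200 genes, 6702 had more than 1 probe set, and the probe set with the highest mean over all 8 arrays stood for the gene. Probe sets of multigene families (for example Ly6i, Cyp2a4 and Cyp2a5, Stfa2l1, the Serpina3, Bcl2a1, Clec4 and H2ac genes) can bind transcripts of close relatives, so the identity of the gene is uncertain there.

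Values were taken to log2 and tested gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), dox against water, with Benjamini-Hochberg adjustment over all 27200 genes and a threshold of 0.05. Changes are log2 differences of dox minus water with limma's standard error (SE), levels are geometric means of intensity, and spreads are SDs over 3 water and 5 dox arrays. "Rose" and "fell" are used of genes past the threshold. The 40 gene lists with 834 genes, the design, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with camera (preset correlation between genes of 0.01, 2-sided, adjusted over the 40 lists), again with a correlation estimated for each list, and with the rotation test fry. The rule named Il1b and up to 6 further IL-1 family members, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, and for each list the 2 largest changes in its main direction and the largest in the other, or the member with the smallest p where none passed. Other genes named as list members were chosen after their values were seen. The result of 1 of the 16 gene families counted is not reported here.

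The computation was tested on simulated data: 8 arrays were drawn from the means and spreads of the 27200 genes for dox against water, with 200 genes changed. The test found 64% of genes changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 3-fold or 4-fold, with 15 unchanged genes among 196 calls. Genes were drawn independently with normal noise, unlike real genes, so these shares need not hold for the real arrays. Alternatives were another prior (trend and robust), array weights, repeated quantile normalization, subtraction of array medians, removal of the dimmest 25% of genes, the mean of a gene's probe sets, every probe set on its own, the replicate number as a block, and each array left out in turn. Permutation tests, exact tests and bootstrap intervals used numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.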

Results

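Gene expression was measured in whole lungs of transgenic mice in which doxycycline turns on interleukin-1b (IL-1b), a cytokine that starts acute inflammation. The series holds 5 dox arrays and 3 water arrays, and its comparison asks which lung transcripts differ once the transgene has been induced for 7 days. Dox-treated mice without the transgene were not analysed here, so effects of doxycycline and of IL-1b are not separated. Arrays of 1 group correlated with r from 0.994 to 0.997 over probe sets, and arrays of different groups with r from 0.990 to 0.995. No pair of arrays held identical values. The labels call the samples replicates of lungs from treated mice without saying that each is a separate animal, and the p-values measure the spread between these samples.

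Induced lungs held far more transcript of some chemokines, acute-phase proteins and mucous cell products. Cxcl5, a chemokine that attracts neutrophils, rose from 15.1 to 1052 intensity units (at least 69.6-fold; log2 change 6.12 ± 0.22 SE, adjusted p = 2.41e-07). Saa3, an acute-phase serum amyloid, rose 49.3-fold (5.62 ± 0.18 SE), and Clca1, a secreted product of mucous cells, rose 46.0-fold (5.52 ± 0.74 SE) with a wide spread in both groups (SD 1.39 in water and 1.29 in dox on the log2 scale). The log2 change of Clca1 was 4.86 without water 2, where its value was near the floor (log2 2.98), and 6.24 without water 3. The size of its rise is thus uncertain. Water means of Cxcl5 (15.1), Ccl7 (14.9), Il6 (14.97), Sele (14.4), Cyp7b1 (16.1) and Stfa2l1 (13.3) lay near the lower quartile of all probe sets (13.9 to 14.5 units), where signal is not shown to exceed background, so their changes are lower bounds. Further large log2 rises were those of Cxcl1 (4.59), Ly6i (4.33), the neutrophil surface protein Cd177 (3.96), the anion exchanger Slc26a4 (3.68), the siderophore-binding lipocalin Lcn2 (3.45), Cxcl3 (3.42) and the lectin Itln1 (3.26). The value of Itln1 in water 2 was also near the floor (log2 3.90), so the size of its rise is uncertain. In all, 1359 of 27200 genes passed the threshold, 946 higher and 413 lower in dox, and 192 rose against 8 that fell by 2-fold or more. Leaving out water 2 left 893 genes, and the lower genes numbered 211 without water 1, 212 without water 2, 265 without dox 1, 224 without dox 2 and 260 without dox 5. No overlap between the groups was seen for 14.2% of genes, against 3.57% by chance. Among the called genes, 426 had several probe sets, and none of them had another probe set called in the other direction. A further probe set did not always pass, however. On their own, 1 of 2 passed for Mmp12, Cdk1, Il1rl1 and Phex and 2 of 3 for Cntn1, but 3 of 3 for Hhip and Icos.

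**Figure D1:**
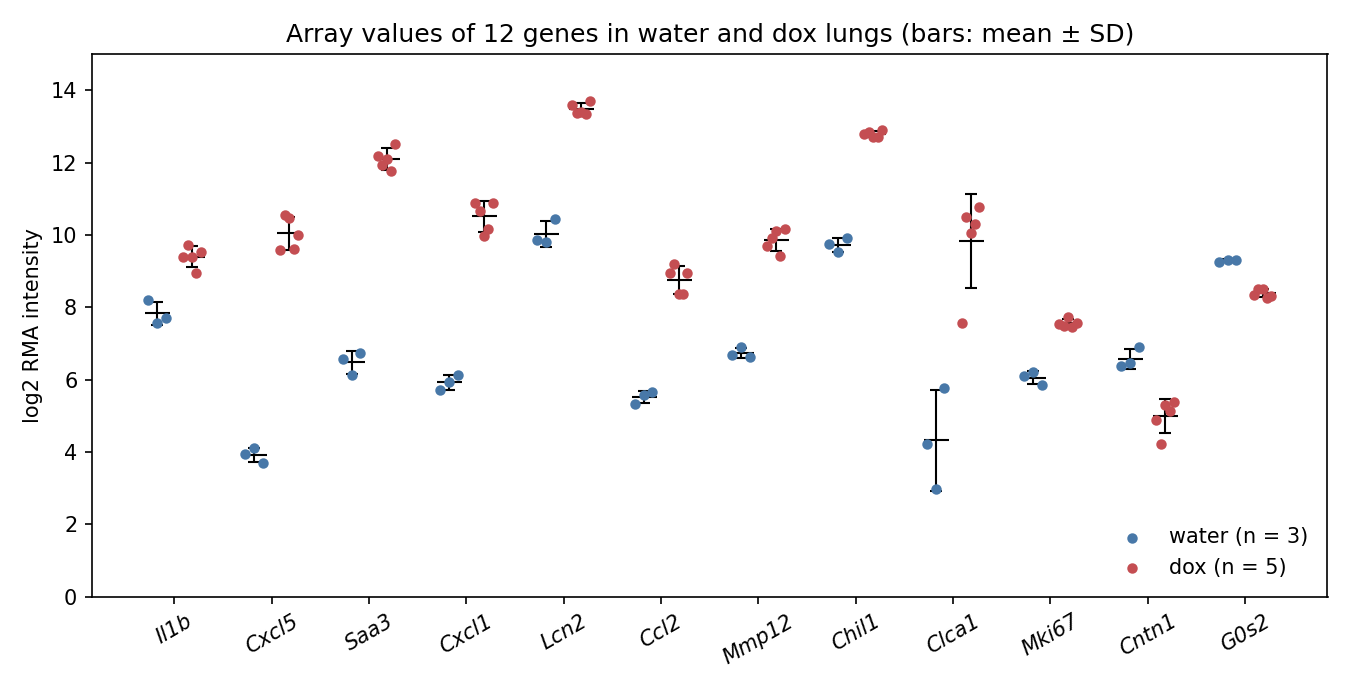
Log2 RMA intensity (vertical axis) of 12 genes (horizontal axis) on each water array (n = 3, blue) and dox array (n = 5, red), with the mean and SD of each group as black bars. Cxcl5 went from a mean of 3.92 to 10.04, Clca1 varied most within each group, and Cntn1 and G0s2 were lower on every dox array than on any water array.

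Falls of 2-fold or more were few. The neuronal adhesion protein Cntn1 fell by 1.60 on the log2 scale (SE 0.24, from 95.6 to 31.6 intensity units, adjusted p = 0.00309), and Bex2 fell by 1.38 (SE 0.24). Phex, a membrane endopeptidase, fell by 1.00. Falls that also passed the threshold but lost it when single arrays were left out were those of Cyp2a4 (-1.49, without water 1, 2 or 3 or dox 1, 2 or 3, adjusted p up to 0.149), the sulfotransferase Sult1d1 (-1.29, without water 3, 0.0634), the iron hormone gene Hamp (-1.27, without water 1, 2 or 3 or dox 2 or 5, up to 0.0949) and the lipogenic gene Thrsp (-1.19, without water 1, 2 or 3 or dox 2, 3 or 5, up to 0.155). The same held for Cst8 (-1.18, without water 2 or 3, up to 0.0757), the BMP antagonist Chrdl1 (-0.95, without water 1 or 2, up to 0.075) and Zc3h6 (-0.96, without water 1 or 2 or dox 1, 2, 3 or 5, up to 0.139).

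The probe set for the mouse Il1b gene rose 2.96-fold, from 227 to 673 intensity units (log2 change 1.57 ± 0.17 SE, adjusted p = 0.000525), and all 5 dox values lay above all 3 water values. The labels do not say whether the transgene is of mouse or human origin, so this probe set can hold the endogenous gene alone. Of 19 measured members of the IL-1 family and its receptors, 10 rose, and 10 did so adjusted over the list alone. Camera gave an adjusted p of 4.8e-09, and of 0.038 with an estimated correlation. The members that rose included the decoy receptor Il1r2 (1.21), Il1a (0.99), the receptor antagonist Il1rn (0.92), the IL-33 receptor Il1rl1 (0.86), the processing protease Casp1 (0.67) and Il18 (0.63). Among NF-kB target and feedback genes, 16 of 23 rose (19 adjusted over the list alone, camera adjusted p = 6.69e-25, adjusted p = 0.0339 with an estimated correlation). Among them were the IkB family member Nfkbiz (1.47 ± 0.09 SE) and Il6 (at least 1.77 ± 0.35 SE). The Il6 call was lost without water 1, 2 or 3 (adjusted p up to 0.0594).

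Chemokines of several classes rose. Of 13 neutrophil-attracting chemokines and growth factors, 5 rose (5 adjusted over the list alone, camera adjusted p = 7.78e-09), namely Cxcl5, Cxcl1, Cxcl3, Cxcl2 (3.23) and the growth factor Csf2 (1.74), while Csf3 changed by 0.03 and did not pass (adjusted p = 0.923). Of 12 monocyte-attracting chemokines, 8 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 3.05e-11): Ccl2 rose by 3.24 and Ccl7 by at least 2.94, and the epithelial chemokine Cxcl14 fell by 0.68, a call lost without water 1 or 2 (up to 0.069). Of 17 lymphocyte-attracting chemokines, 9 rose (11 adjusted over the list alone, camera adjusted p = 2.77e-12), with Ccl17 at 2.47, Ccl20 at 2.40 and the B cell chemokine Cxcl13 at 1.88. Of 13 endothelial adhesion molecules, 4 rose (7 adjusted over the list alone), among them the selectins Sele (at least 1.26) and Selp (1.07); without water 3, 2 of the 4 passed. The camera adjusted p was 0.00036 for that list, and the adjusted p was 0.0899 with an estimated correlation.

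Of 29 acute-phase and complement genes, 22 rose (23 up and 1 down adjusted over the list alone, camera adjusted p = 2.66e-32, adjusted p = 0.0179 with an estimated correlation). Complement factor Cfb rose by 2.07 (SE 0.08), and the C1q subunits C1qa, C1qb and C1qc by 1.93, 2.03 and 2.01, while 1 member fell without water 2 or dox 4; these 3 also stand in the macrophage list, and 6 of the 29 genes stand in other lists. Of 19 secreted antimicrobial proteins, 9 rose (12 up and 1 down adjusted over the list alone, camera adjusted p = 2.03e-12), led by Lcn2 and the bactericidal lectin Reg3g (3.14 ± 0.26 SE). In that list the airway protein Bpifa1 had a log2 change of -2.57 with a large spread (SD 1.63 in water and 1.04 in dox) and did not pass (adjusted p = 0.0667). It passed without water 2 (-3.39, adjusted p = 0.0248) or dox 4 (-2.90, 0.042), and with the replicate number as a block (-3.13, 0.0105). Its log2 change ran from -3.39 to -1.75 over the alternatives.

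Of 31 matrix metalloproteinases and other proteases, 10 rose (12 up and 1 down adjusted over the list alone, camera adjusted p = 5.43e-10). Without water 3, 1 member fell. Mmp12, the macrophage elastase, rose 8.69-fold (3.12 ± 0.15 SE) and Mmp8, the neutrophil collagenase, 5.11-fold (2.35 ± 0.20 SE). Of 26 protease inhibitors, 5 rose (6 adjusted over the list alone, camera adjusted p = 0.000558, adjusted p = 0.0598 with an estimated correlation), with Timp1, an inhibitor of metalloproteinases, at 2.37 and Itih4 at 1.53. Of 22 elastic fibre genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.578; 0.0495 without water 2). Ltbp4, which guides elastin assembly, fell by 0.52. Emilin2 rose by 0.62, a call lost without water 2 or 3 (up to 0.0789), and Ltbp1 by 0.35, lost without any array but dox 1 (up to 0.152). Eln itself had a log2 change of 0.78 ± 0.26 SE and did not pass (adjusted p = 0.127), though it did without water 2 (0.0239). Of 31 collagens and other matrix genes, 4 rose and 1 fell (9 and 3 adjusted over the list alone). Camera gave an adjusted p of 0.0038 for that list, but 0.0816 without water 3 and an adjusted p of 0.503 with an estimated correlation. Osteopontin, Spp1, rose by 0.93; Vcan rose by 1.15, lost without water 1 (0.063); Col4a4 fell by 0.40, lost without water 1 or 2 or dox 1, 2 or 5 (up to 0.119). Without water 1, 2 members of that list rose.

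Many markers of phagocytes rose. Of 31 macrophage and monocyte markers, 22 rose (25 up and 2 down adjusted over the list alone, camera adjusted p = 7.71e-30, adjusted p = 0.0179 with an estimated correlation). Mmp12 and the endotoxin co-receptor Cd14 (2.40 ± 0.15 SE) were in front, and 1 marker fell without dox 4. Of 28 neutrophil markers, 15 rose (17 up and 1 down adjusted over the list alone, camera adjusted p = 5.12e-14, adjusted p = 0.0601 with an estimated correlation), with Mmp8 and, by at least 1.60, the stefin Stfa2l1; 9 rose without water 2 and 9 without water 3. The elastase gene Elane, made by immature neutrophils, had a log2 change of 0.16 and did not pass (adjusted p = 0.356). Of 20 dendritic cell markers, 8 rose (12 adjusted over the list alone, camera adjusted p = 2.31e-10), with Ccl17 and the maturation marker Cd83 (1.39). MHC class II genes rose in 9 of 11 cases (9 adjusted over the list alone, camera adjusted p = 4.36e-14, adjusted p = 0.0626 with an estimated correlation), among them H2-DMa (0.93) and H2-Ab1 (0.90).

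Lymphocyte, NK cell and granulocyte lists other than neutrophils did not pass. Of 24 T cell markers, 1 rose, the costimulatory receptor Icos at 0.56 (2 adjusted over the list alone, camera adjusted p = 0.614). Its call was lost without water 1, 2 or 3 or dox 3 or 5 (up to 0.116), and the list passed upward without water 1 (0.000919). Of 22 B cell and plasma cell markers, 2 rose (3 up and 1 down adjusted over the list alone, camera adjusted p = 0.47; 0.0317 downward without water 3). They were the IgE receptor Fcer2a at 1.29 (0.85 without water 3), lost without any array but water 1 (up to 0.128), and Xbp1 at 0.41, lost without water 1 (0.0586). Of 19 NK and cytotoxic cell markers 0 passed in limma, in the list alone or over all genes, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.755). It was Klrg1 (0.31, adjusted p = 0.0985), which passed without dox 1 (0.0157). Of 17 eosinophil and mast cell markers, 1 rose (1 up and 1 down adjusted over the list alone, camera adjusted p = 0.958), Siglecf at 0.47, which alveolar macrophages also carry and which lost its call without water 2 or 3 (up to 0.081); 1 other marker fell without water 2. The T cell and eosinophil lists had medians of -0.02 and -0.01, while camera placed them upward.

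Proliferation genes rose in 23 of 31 cases (28 adjusted over the list alone, camera adjusted p = 2.33e-32, adjusted p = 0.0179 with an estimated correlation). The cycling-cell antigen Mki67 was up 2.82-fold and the mitotic kinase Cdk1 rose by 1.08 ± 0.10 SE. Of 31 interferon-response genes, 11 rose (15 up and 1 down adjusted over the list alone, camera adjusted p = 1.29e-09, adjusted p = 0.0899 with an estimated correlation), led by the GTPase Iigp1 (0.92) and the nucleic acid sensor Zbp1 (0.78); 7 rose without water 2 and 6 without water 3, and 1 fell without dox 4. Of 25 genes of prostaglandin, leukotriene and nitric oxide synthesis, 9 rose and 1 fell (9 and 3 adjusted over the list alone, camera adjusted p = 1.36e-05). The arginases moved apart, Arg2 rising by 1.26 and Arg1 falling by 0.70, thromboxane synthase Tbxas1 rose by 0.97, and the inducible enzymes Ptgs2 (0.28) and Nos2 (0.09) did not pass. Of 17 alternative activation and type 2 genes, 6 rose (8 adjusted over the list alone, camera adjusted p = 2.21e-07), with the chitinase-like protein Chil1 at 3.06 ± 0.09 SE and the lectin Clec10a at 1.17.

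Of 26 cytochrome P450 and xenobiotic metabolism genes, 6 fell and 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 4.17e-07, adjusted p = 0.175 with an estimated correlation); Cyp2a4 and Sult1d1 fell most, the oxysterol hydroxylase Cyp7b1 rose by at least 1.32, and 2 fell without water 3. Of 25 antioxidant genes, 3 rose and 1 fell (6 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.126; 0.0153 upward without water 3). The falls numbered 2 without dox 1 or dox 4, and with the trend and robust prior 5 rose and 4 fell. Metallothionein Mt2 rose by 1.44, the cystine transporter Slc7a11 by 0.71, and Gstm1 fell by 0.57. Of 24 amino acid and mitochondrial stress genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00265, adjusted p = 0.199 with an estimated correlation, 0.0737 without water 1). Slc7a11 and the serine synthesis enzyme Psat1 (0.52) rose, and the transcription factor Atf5 fell by 0.47, a call lost without water 1, 2 or 3 or dox 1, 2 or 3 (up to 0.092). Of 29 measured oxidative phosphorylation genes 0 passed in limma, over all genes or in the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.734). It was Cox5a (0.22, adjusted p = 0.0814), which passed with the trend and robust prior.

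Of the airway cell lists, that of mucous cells passed upward, and those of club and ciliated cells did not pass. Of 20 mucous cell markers, 8 rose (13 adjusted over the list alone, camera adjusted p = 3.23e-14), including Clca1, Slc26a4, the disulfide isomerase Agr2 (2.82) and the mucin Muc5b (1.06 ± 0.22 SE; lost without water 1, 0.0902, or water 2, 0.0666, and with the trend and robust prior), whereas the mucin Muc5ac changed by 0.07 and did not pass (adjusted p = 0.717). Of 20 club cell markers, 2 fell and 1 rose (2 and 2 adjusted over the list alone, camera adjusted p = 0.237; 0.021 downward without water 1). Paraoxonase Pon1 fell by 0.64. The other fall, Cyp2a5, which also counts in the P450 list, had both means under the lower quartile (10.9 and 8.21 intensity units), so its size has no meaning, and it was lost without water 3 (0.0616). Nupr1 rose by 0.30, lost without water 1 or 3 or dox 1, 2, 3 or 4 (up to 0.106). Of 25 ciliated cell markers, 1 fell, Tppp3 at -0.40 (1 adjusted over the list alone, camera adjusted p = 0.196; 0.000433 without water 1 and 0.0152 without dox 5, both downward).

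Alveolar type 1, endothelial and fibroblast markers were lower as lists, by small amounts. Of 22 alveolar type 1 markers, 2 fell (10 adjusted over the list alone, camera adjusted p = 5.74e-07, adjusted p = 0.128 with an estimated correlation). They were Igfbp6 (-0.51, lost without water 1 or 3 or dox 2 or 5, up to 0.114) and Sema3a (-0.31, lost without any array but dox 4, up to 0.155). Type 1 falls numbered 0 without water 1, water 3, dox 2 or dox 5, and 1 without water 2, dox 1 or dox 3. Of 28 endothelial markers, 4 fell (16 adjusted over the list alone, camera adjusted p = 1.46e-07, adjusted p = 0.144 with an estimated correlation), among them the endothelin receptor Ednrb (-0.57, lost without water 1 or 2 or dox 1, 2 or 3, up to 0.131) and Gpihbp1 (-0.43, lost without any array but dox 1, up to 0.147). That count was 1 without water 1 or dox 5, 2 without dox 4, and 0 without water 2, dox 2 or dox 3. Of 25 fibroblast and mesenchymal markers, 6 fell and 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 1.44e-07, adjusted p = 0.138 with an estimated correlation). G0s2, an inhibitor of lipolysis, fell by 0.91 (SE 0.07), Col14a1 rose by 0.44, and the transcription factor Tcf21 fell by 0.44, lost without water 2 or 3 or dox 1, 2, 3 or 5 (up to 0.165). The number of falls was 3 without water 1, dox 1, dox 2 or dox 3, and 2 without water 2. In the type 1, endothelial and fibroblast lists, 7, 9 and 10 members fell with the trend and robust prior, and 0, 2 and 5 with array weights.

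The alveolar type 2 list did not pass. Of 23 measured, 5 rose (5 up and 2 down adjusted over the list alone, camera adjusted p = 0.099), with Chil1 first and the collectin Sftpd at 0.44 ± 0.07 SE; 3 rose without water 1 and 3 without water 2. The surfactant gene Sftpc changed by -0.01 at an intensity of 25850, near the top of the scale, where differences are compressed. The list median was 0.01, against -0.22 for alveolar type 1, -0.22 for endothelial and -0.26 for fibroblast markers.

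**Figure D2:**
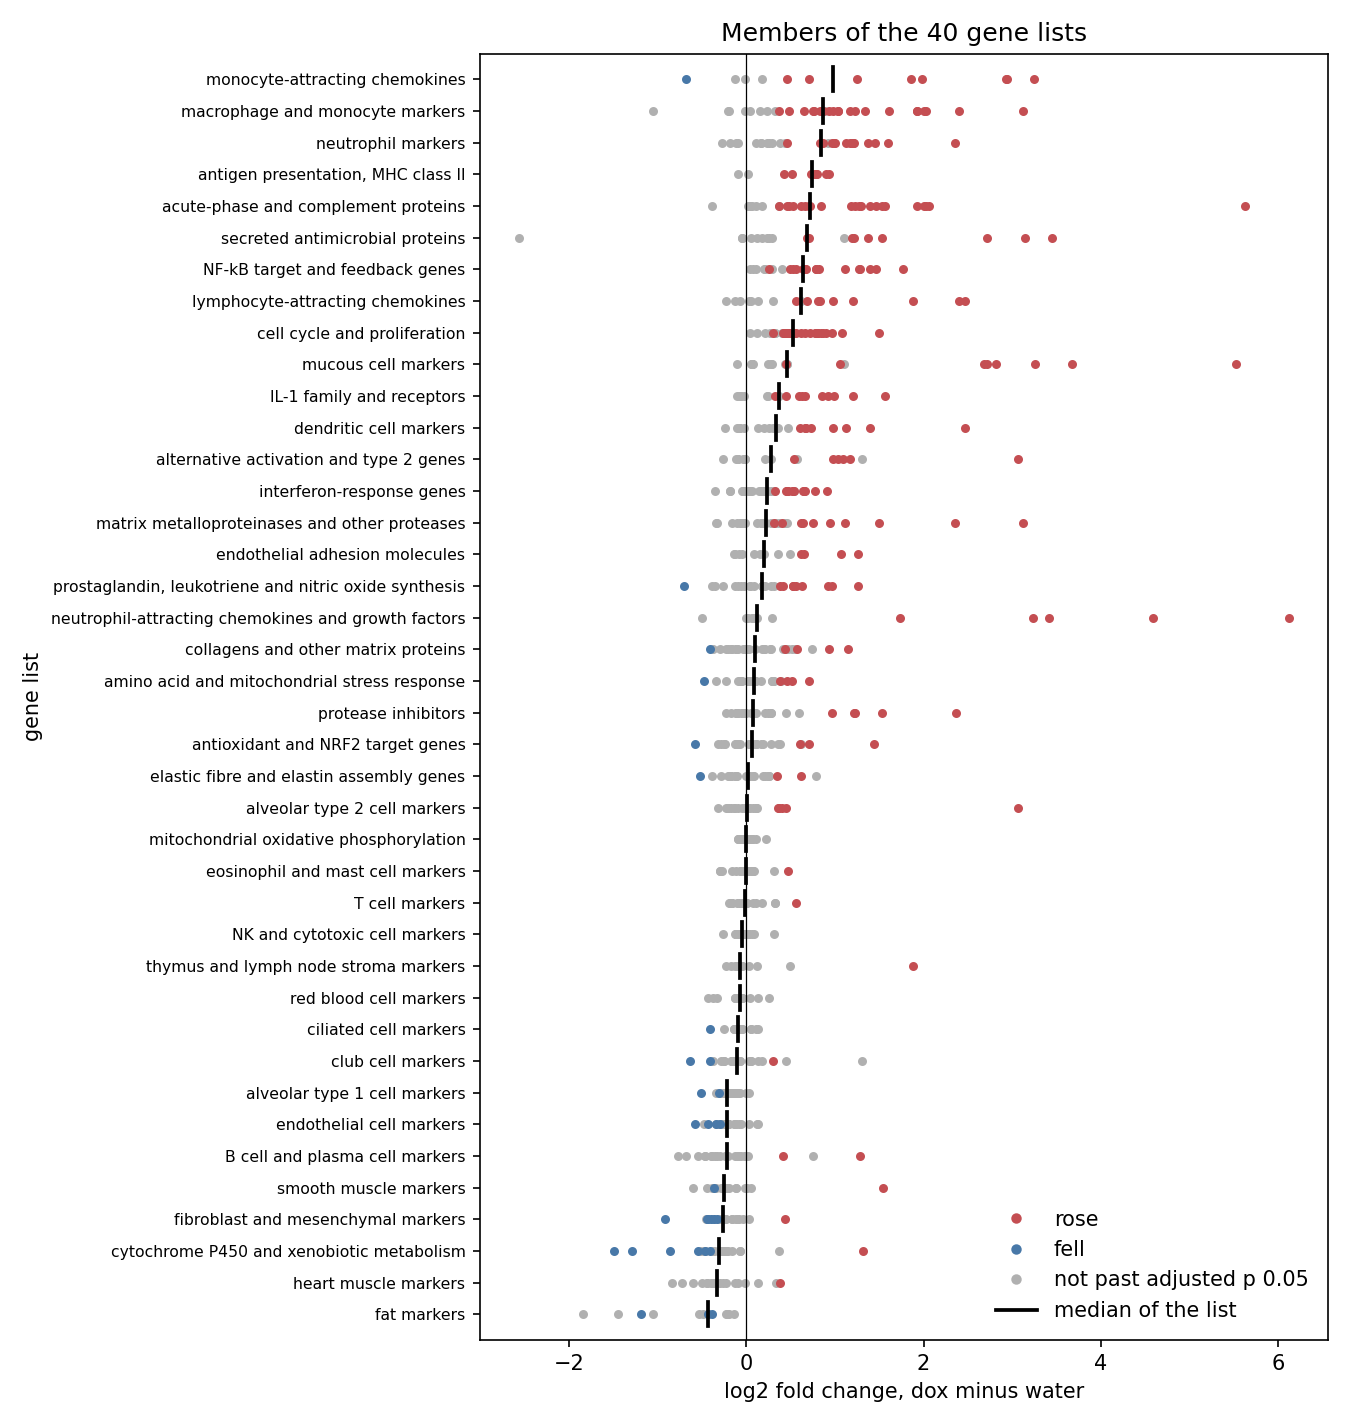
Log2 fold change, dox minus water (horizontal axis), of each measured member of the 40 gene lists (vertical axis, ordered by median), with red points for genes that rose, blue for genes that fell, grey for the rest and a black bar at each list's median. Monocyte-attracting chemokines had the highest median (0.98) and fat markers the lowest (-0.44).

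Markers of other tissues were also measured. All 13 fat markers had lower means in dox lungs, and 3 fell (10 adjusted over the list alone, camera adjusted p = 6.8e-07, adjusted p = 0.0899 with an estimated correlation). They included Thrsp and Cidea (-0.44, lost without water 2 or 3, up to 0.0575). Adipoq (-1.84) and Cfd (-1.45) varied between dox arrays (SD 1.08 and 0.95) and did not pass (adjusted p = 0.0639 and 0.0966). Both did without dox 4 (0.00049 and 0.000674) and with the replicate number as a block (0.000295 and 0.00403). The count of falls was 0 without water 3, 7 without dox 4, and 1 without water 1, water 2, dox 2, dox 3 or dox 5. The mean of the 20 heart muscle markers relative to water ran from -0.91 to 0.47 between dox arrays; 1 member rose, Myh7 at 0.38, and 0 with the mean of a gene's probe sets (1 adjusted over the list alone, camera adjusted p = 0.189; 0.000652 downward without dox 4, with 1 fall). Of 17 smooth muscle markers, 1 rose and 1 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.0101, adjusted p = 0.439 with an estimated correlation, 0.125 without water 2). The hedgehog-binding protein Hhip rose by 1.54 ± 0.09 SE, and Mustn1 fell by 0.36, lost without water 1 or 3 or dox 1, 3 or 5 (up to 0.117). Falls of that list numbered 2 without water 1 or dox 4, and 3 with the trend and robust prior, with repeated quantile normalization or without the dimmest 25% of genes. Of 12 red blood cell markers 0 passed in limma, over all genes or in the list alone, and 1 had an unadjusted p under 0.05, Tfrc (0.26, adjusted p = 0.221; camera adjusted p = 0.505 for the list). Of 13 thymus and lymph node stroma markers, 1 rose, Cxcl13 (2 without water 2 or dox 1; 2 adjusted over the list alone, camera adjusted p = 0.583, with a median of -0.07 and an upward camera direction).

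Of the 40 lists, 27 passed with camera, 21 upward and 6 downward, and 14 of them with an estimated correlation. For these 14, the adjusted p with an estimated correlation ran from 0.0179 to 0.0389. Their far smaller camera values thus hold only under the preset setting, but the size of the correlation alone does not explain the gap. For the prostaglandin list it was estimated at -0.000124, under the preset 0.01. Yet the camera adjusted p of that list went from 1.36e-05 to 0.0179. With fry, which tests a list's own genes without setting them against others, 25 passed in 1 direction and 34 in either direction. The alveolar type 2 list passed upward in fry (adjusted p = 0.00144), while the collagen (0.257), amino acid stress (0.0525) and smooth muscle (0.355) lists did not. Many lists share genes, so those that passed are not all separate evidence. Members in other lists numbered 11 of 28 neutrophil markers, 9 of 19 secreted antimicrobial proteins and 7 of 31 macrophage markers. The MHC class II and proliferation lists shared 0.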

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

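The tests on airway content, on fat tissue, on the 3 falling lists alone, on members under a mean log2 value of 12 and on differences array by array were chosen only after the results were seen. In a group of 5 arrays a gap this wide sets an array apart in about 1 of 20 groups by chance, and 4 of 92 named genes and 1 of 40 lists did so here. Dox 1 held the lowest value of Clca1 (log2 7.57 against 10.05 for the next, a gap of 0.775 of the range), Phex (gap 0.784) and Cxcl14 (gap 0.897), and the lowest mean of the collagen list (-0.05 against 0.20 for the next, gap 0.819). Dox 5 held the highest value of Arg2 (8.28 against 7.81, gap 0.744). Among probe sets without a single gene symbol, which the comparison of genes did not use, 32 of 6688 passed the threshold when every probe set was tested on its own, 17 higher and 15 lower in dox.

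The number of genes between the groups was set against every division of the 8 arrays into 3 and 5. Only the real one of the 56, 1 split, gave as many as 1359 genes, and the highest of the others gave 2. The exact permutation p was 0.0179, the smallest possible, so chance is argued against for the count but not excluded. Every other split mixes water and dox arrays in a group, which widens its spread, so the size of the gap adds little.

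Lower levels of resident lung cell markers could come from dilution by RNA of incoming leukocytes, which would lower all resident types alike. The ranked changes of the 6 resident lists differed (permutation of the members' list labels, p = 1e-05, the smallest that 100000 permutations can give; p = 8e-05 for members with a mean log2 value under 12, where the scale is less compressed), with genes treated as independent although they are not. Between arrays, the spread of the 6 dox minus water medians was matched by 13 of the 56 splits (exact permutation p = 0.232). Unequal change over the 6 lists together was thus not shown beyond the spread between arrays. The alveolar type 2 median minus the type 1 median was higher in every dox array (0.107 to 0.277) than in water (-0.029 to 0.036). The exact permutation p was 0.0179, the smallest possible, without adjustment for the choice of this pair. The pair was picked after the values were seen, and the comparison of all 6 lists between arrays did not show unequal change. The difference for this pair thus does not decide whether dilution was equal. As the whole cause or a part of it, dilution stays open for all 6 lists. The alveolar type 1, endothelial and fibroblast lists were picked because they fell, so their likeness (permutation p = 0.243) decides nothing about those falls. A loss or altered state of these cells in induced lungs is an untested biological explanation.

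The rise of mucous cell markers could come from more conducting airway in the dox samples, which would raise ciliated markers as well. The median change of the ciliated list was -0.09 (-0.22 without water 1, 0.10 without water 3) against 0.46 for the mucous list (0.43 and 0.50); its upper 95% bootstrap bound of -0.066 covers the choice of genes and not the spread between arrays. Array by array, the mucous median minus the ciliated median was higher in all 5 dox arrays (0.45 to 0.64) than in water (-0.30 to 0.23; exact 2-sided permutation p = 0.0179, the smallest possible). More airway of the kind present in water lungs is thus argued against as the whole cause, and a changed state of airway cells after induction remains a hypothesis. Of the 20 mucous markers, 2 also stand in another list, and the ciliated list shares none.

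Lower fat markers could come from less fat tissue carried along with the dox lungs. Across the 8 arrays, Adipoq and Cfd deviated together from their group means (Pearson r = 0.971, exact permutation within groups p = 0.00556, adjusted 0.0167 over 3 relations). Spearman rho was 0.833 (p = 0.0181, adjusted 0.0542), and r was 0.749 without the 2 arrays farthest in Adipoq. Both are products of fat cells, so they would vary together whether fat was carried along or changed inside the lung. Deviations within groups also do not address the fall between groups, so the relation decides nothing about its cause. The mean of the fat list relative to water ran from -0.013 to 0.016 in water and from -0.96 to -0.156 in dox arrays. Adipoq had mean levels of 228 in water and 63.6 in dox lungs, and Cfd of 1078 and 394. The fat list without Fabp4, which macrophages also express, was not detectably related to the heart list (r = 0.790, p = 0.101, adjusted 0.152; rho = 0.714, p = 0.153, adjusted 0.229; r = 0.289 without the 2 farthest), nor was Adipoq (r = 0.577, p = 0.274, adjusted 0.274; rho = 0.286, p = 0.561, adjusted 0.561; r = 0.523 without the 2 farthest). A fall of fat transcripts inside the lung was not tested and stays open.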

How the results depend on the processing

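No alternative in this part was chosen after the results were seen. Il1b kept its direction and passed under every alternative run (log2 change 1.44 to 1.75), and the number of genes past the threshold with a 2-fold change stayed between 182 and 224. The number of genes past the threshold ran from 893 to 1290 with 1 array left out, and the number of lower genes from 211 to 410; fewer arrays enter these fits. The number of lower genes was 664 with the trend and robust prior, and the cause was not tested. The number of lists was 14 with an estimated correlation. With the replicate number as a block, 606 genes passed, 505 higher and 101 lower, and 560 of them were called without it. That fit uses up degrees of freedom. Numbers 4 and 5 occur only in dox, so its change rests on the arrays numbered 1 to 3. The numbers showed no pairing of the samples: deviations of arrays with the same number correlated at 0.011, 0.036 and -0.109. Not every array correlated best with its own number, and the highest correlation between groups was that of water 3 and dox 5 (0.244). Subtracting array medians moved the share of higher genes from 69.6% to 78.2% and the median log2 change of all genes from -0.025 to -0.002. Over the named genes other than Il1b, 1201 values under alternatives kept direction and side of the threshold, 161 lost the threshold, 2 gained it and 0 reversed; of 89 named genes that passed, 62 did so whichever array was left out. Among named genes, Cyp2a4, Sult1d1, Hamp, Thrsp, Zc3h6, Il6 and Fcer2a lost the threshold with the trend and robust prior, and Cyp2a4, Thrsp, Zc3h6, Ltbp1, Igfbp6, Sema3a, Gpihbp1 and Mustn1 with array weights. Zc3h6, Col4a4, Tcf21 and Myh7 lost it with the mean of a gene's probe sets, Zc3h6, Sema3a, Gpihbp1 and Tcf21 with array medians subtracted, and Zc3h6 with repeated quantile normalization. With the replicate block, Il1rn, Stfa2l1, Sftpd, Pon1, Tppp3, Col14a1 and Myh7 lost it, though they passed whichever array was left out. So did Cst8, Zc3h6, Cxcl14, Emilin2, Ltbp1, Col4a4, Fcer2a, Xbp1 and Siglecf lose it with the block. Igfbp6, Sema3a, Cyp2a5, Nupr1, Ednrb, Gpihbp1, Tcf21, Mustn1 and Cidea did as well. Set tests used the trend alone, since camera has no robust prior. The planned use of a second table of values was not run, because its columns could not be matched to samples. Leaving out the dimmest 25% of genes gave 1591 calls among 20400; signal over background limits what can be said of genes at the floor.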

Other observations

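The gene families here were chosen after the values were seen, so counts are given and their enrichment tests are not used, beside 946 rises and 413 falls among all 27200 genes. Of 9 Fc receptor genes, 6 rose, among them the inhibitory receptor Fcgr2b (2.03 ± 0.14 SE) and the activating Fcgr3 (1.29) and Fcgr1 (1.23). Of 20 paired and inhibitory myeloid receptors, 12 rose and 1 fell, with Lilrb4a at 1.45 and Pilra at 0.96, and of 32 C-type lectin receptors 10 rose and 2 fell, with a family median of 0.04. Of 12 Toll-like receptors, 5 rose, including Tlr2 (1.16 ± 0.10 SE) and Tlr13 (1.09, lost with the replicate number as a block, adjusted p = 0.0565). Of 57 replication-dependent histone genes, 10 rose, although their probe sets cannot tell near-identical copies apart.

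Among single genes outside the lists, also chosen after their values were seen, the metalloreductase Steap4 (3.19 ± 0.17 SE), the amino acid transporter Slc6a20a (2.94 ± 0.09 SE), the pantetheinase Vnn1 (2.78 ± 0.17 SE), the NADPH oxidase organizer Noxo1 (2.16 ± 0.08 SE) and the estrogen receptor Esr1 (1.54 ± 0.13 SE) rose. Of 45 BMP pathway genes 5 fell, among them Gdf10 (-0.86), Bambi (-0.68) and Bmper (-0.67). The mesenchymal transcription factor Snai2 fell by 0.92 (SE 0.07). The transcription factor gene Nr4a1 fell by 0.90 and Egr2 rose by 1.22. In further families the counts were 6 rises among 31 integrins, 5 rises and 1 fall among 20 Ms4a genes, 23 and 11 among 377 solute carriers, 3 and 1 among 20 TNF receptors, and 4 and 1 among 96 potassium channels. Falls numbered 3 of 42 Hox genes, 3 of 20 semaphorins with 1 rise, 2 of 24 dual-specificity phosphatases and 1 of 22 fibroblast growth factors.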
